A study of Drosophila melanogaster with 2 samples.

How the data were processed

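CLAMP-GFP ChIP-seq was available for 1 group of 2 biological replicates, numbered 4 and 2 in the labels, from whole embryos of both sexes aged 0 to 24 h. Chromatin was fragmented by sonication to 200 to 800 bp, per the labels, and the labels of replicate 2 cite 1 protocol document more than those of replicate 4. No other condition or untagged line was analysed here.

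The starting point was 8 deposited lists of peaks: for each of the builds dm6 and dm3, a list per replicate, a list from both replicates pooled, and an optimal set. Per the deposited text files, each replicate's list was made from that replicate's alignment and 1 control file, and the pooled list from both alignments and the same control. The optimal set was made from these lists by an irreproducible discovery rate step, per the same text files. The aligner, the peak caller and the threshold of that step are not given in the sources used here. The first 3 kinds of list contain background regions besides peaks, by their deposited description. Each peak carries a signal value, an enrichment as the authors' caller gave it; whether it was scaled to read depth is not given in the sources used here. The signal is the authors' own value and was used only to describe and rank peaks within a list. The score in the deposited lists is a significance column whose top values are tied, and it falls below 0 in the dm6 list of replicate 2 (19306 of 30000 regions), so it was not used to filter peaks.

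The 3077 optimal peaks in dm6 were identical in position and signal to peaks of the pooled list, and no other pooled peak reached the lowest optimal signal of 123. Peaks were annotated in dm6 only, with the Release 6 genome sequence and the BDGP annotation 6.54 of Ensembl release 115; no dm6 peak ended beyond its chromosome, and dm3 coordinates were not converted. Read depth is unknown from peak lists, so precision is set by the number of sites, and intervals cover counting error or the spread between bins only.

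The comparisons, their tests, the alternatives and 26 gene lists were fixed before the data were examined, except where stated. Gene symbols were matched to the annotation, with 4 older symbols replaced by the current ones. The main set was the 3071 optimal peaks on 2L, 2R, 3L, 3R and X. Summits of the replicates were matched within 200 bp and compared with 1000 circular shifts. X and autosomal density were compared by permuting 1 Mb bins, and median signal by permuting peaks, with 100000 resamples; the intervals came from 10000 bootstrap draws of bins and, for medians, 2000 draws of 1 Mb blocks. TSSs were those of protein-coding and ncRNA transcripts, and a summit within 500 bp of one was called promoter. Other summits were assigned in the order 5' UTR, coding exon, 3' UTR, other exon, intron, intergenic. A GA run was an uninterrupted alternation of G and A, on either strand, of 8 bp or more within 100 bp of a summit, or of 12 bp or more for the count of occupied runs. Gene lists were tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 26 lists at 0.05, counting a gene when a summit lay within 1000 bp of a TSS. As an alternative, each list was compared with 1000 random lists matched on gene length.

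The genes named are those with the TSS nearest to the 20 optimal peaks of highest signal, Clamp, lncRNA:roX1 and lncRNA:roX2, and up to 3 members of each list with the highest signal within 1000 bp of a TSS; a few other members of lists were named after their values had been seen. Results for 2 of the genes that this rule selects are not reported. Alternatives were the 1538 strongest peaks, each replicate alone, and other distances, run lengths, windows and bins. Peaks found in both replicates' lists were added as an alternative after the data had been seen. A peak counted as found when its summit lay within 200 bp of that of any region of the whole list, background regions included. The methods were tested on simulated peaks of the same number. A density ratio of 1.5 was recovered as 1.50 and called in 20 of 20 simulations, a ratio of 1 was called in 1 of 20, and a shared fraction of 60% was found as 61.1%. The peaks of these density simulations were placed uniformly along each arm, without the clustering of the real peaks. Their rates of calls therefore need not hold for clustered peaks. Of 50 simulated gene lists raised from 15 to 40%, 60.0% were called, and of 200 unchanged lists 0.500%. In this simulation peaks were assigned without regard to gene length, and unchanged genes had a 15% share, against 10.3% of the genes here. It therefore cannot show how often a difference in gene length alone leads to a call. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.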

Results

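The occupancy of CLAMP, a zinc-finger protein encoded by Clamp (CG1832) that binds GA repeats and is known for its part in dosage compensation of the male X chromosome, was measured by ChIP-seq in whole Drosophila melanogaster embryos aged 0 to 24 h. The embryos were of both sexes and came from a transgenic line making CLAMP fused to GFP. Chromatin fragments of 200 to 800 bp were recovered with an antibody against GFP. The series held 2 biological replicates, numbered 4 and 2, which formed 1 group with no second condition. The optimal peak set, called from both replicates together, held 3077 peaks, of which 3071 lay on 2L, 2R, 3L, 3R and X. Read depth was unknown, because peak lists carry no read totals. The p-values below measure only the spread between sites or bins in these 2 libraries, since sites are not replicates.

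The strongest CLAMP peak lay in the bithorax complex. The peak with the highest signal value of the optimal set (7590.5) had its summit at 3R:16764189 (dm6; peak 16763904 to 16764429), in an intron of lncRNA:bxd (FBgn0020556) and 9000 bp from the nearest TSS. Strong peaks also lay at oc (FBgn0004102), the head homeobox gene orthodenticle, with a signal of 7546 at X:8650973, 292 bp from a TSS, and at bi (FBgn0000179), a T-box gene, with a signal of 7331 at X:4427014 in an intron. Other peaks of the top group lay near the homeobox genes Ptx1 (6296, 3R:30912590), Lim1 (6044, X:8805965) and unc-4 (6033, X:17768361). A further one, with a signal of 5952 at 3R:16847394, lay in an intron of lncRNA:iab8, again in the bithorax complex.

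Further peaks among the 20 strongest were named by trh, a tracheal bHLH-PAS gene (5833), tio, a zinc-finger gene (5682, in its 3' UTR), tara (5607), tna (5388), the pair-rule gene opa (5335), mts, which encodes a phosphatase subunit (5243), and ap, a LIM-homeobox gene (5150). They ended with Gbeta13F, a G protein subunit gene (5072), D, a Sox gene (4878), the head gap gene btd (4813), eyg, a Pax gene (4811), and the homeobox gene lbe (4804). Of the 20 strongest peaks, 7 were on X, 14 had a summit within 500 bp of a TSS, and 5 of the others were in introns. All 20 were found in both replicates, at rank 27 or better in replicate 4 and rank 44 or better in replicate 2. A GA run of 8 bp or more was present within 100 bp of the summit in 10 of them; the longest, at tna, was 20 bp.

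The Hox gene complexes were densely occupied. The interval from Ubx to Abd-B (3R:16656623 to 16972236, 316 kb) held 26 optimal peaks, or 82.4 per Mb (exact Poisson 95% interval 53.8 to 121), against 20.5 per Mb on the whole of 3R. The Antennapedia complex, from lab to Antp (3R:6661427 to 6999228, 338 kb), held 23 peaks, or 68.1 per Mb (43.2 to 102). Both intervals were chosen after the strongest peaks had been seen. Of the 300 strongest peaks, 9 fell in the bithorax complex and 6 in the Antennapedia complex.

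**Figure D1:**
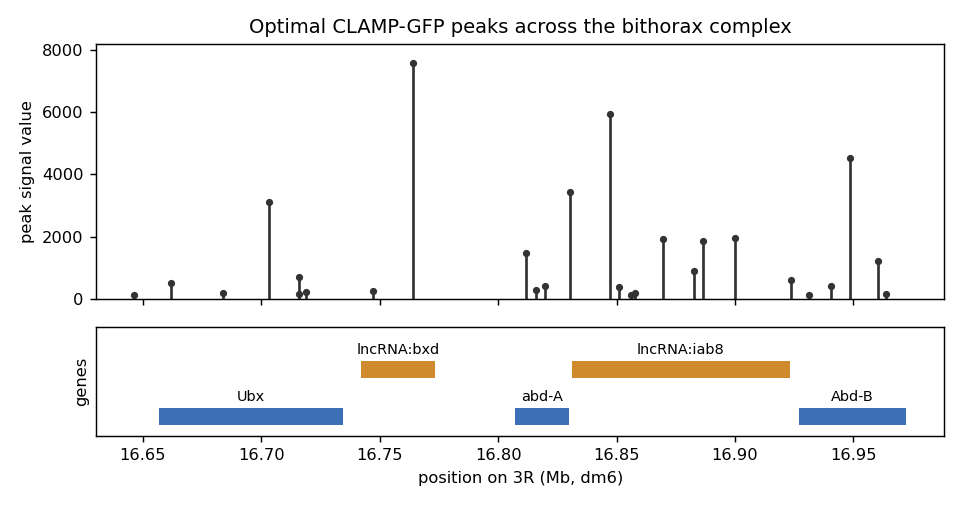
Map of the bithorax complex on 3R (dm6, position in Mb) with the signal value of each optimal peak as a vertical line and the spans of Ubx, abd-A, Abd-B, lncRNA:bxd and lncRNA:iab8 below. The highest lines are the peak in lncRNA:bxd at 7590.5 and the peak in lncRNA:iab8 at 5952.

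The 2 replicates shared most of their strong CLAMP sites. Of the 3077 strongest peaks of replicate 4, 59.2% had a summit within 200 bp of one of the 3077 strongest peaks of replicate 2, against a mean of 0.944% after circular shifts along each arm (permutation p = 0.000999, one-sided, the smallest that 1000 shifts can give). All of the 300 strongest peaks of replicate 4 were found in the whole list of replicate 2. In the other direction 285 of 300 were found, and 15 were missing (5%, exact binomial 95% interval 2.83 to 8.11%). Among the 1000 strongest peaks, 2 of replicate 4 and 152 of replicate 2 were missing from the other list. The 152 missing sites of replicate 2 had a median GC content of 40.7%, and the 848 found sites 46.9%. Across the 2458 optimal peaks found in both lists, the signal values of the replicates had a Spearman rho of 0.795, a correlation across sites, which are not independent replicates.

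**Figure D2:**
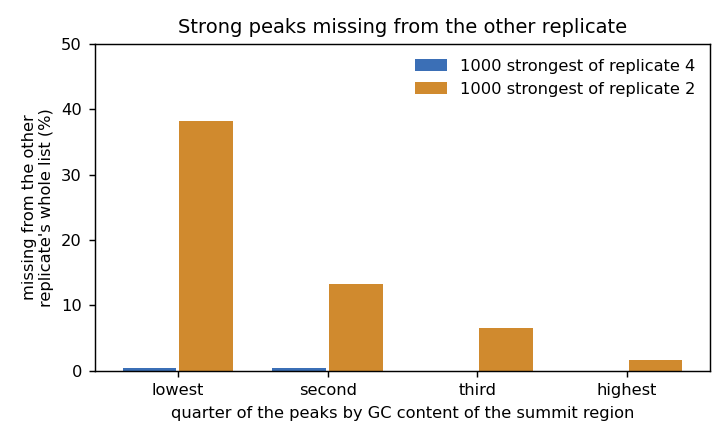
Percent of the 1000 strongest peaks of each replicate with no summit of the other replicate within 200 bp, in 4 equal parts by GC content within 250 bp of the summit. For replicate 2 the bars fall from 38.3% at the lowest to 1.64% at the highest GC content, and for replicate 4 they stay at 0.403% or below.

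CLAMP peaks were denser on X than on the autosomes. X carried 790 optimal peaks, or 33.6 per Mb, and 2L, 2R, 3L and 3R together 2281, or 20.9 per Mb, a ratio of 1.60 (bootstrap 95% interval 1.3 to 1.92 over 1 Mb bins). The 4 autosomal arms lay between 20.1 per Mb on 3L and 22.9 per Mb on 2R. The ratio was above 1 in each replicate taken alone, at 1.35 (1.09 to 1.62) in replicate 4 and 1.76 (1.41 to 2.13) in replicate 2. The two-sided permutation test over 24 X and 112 autosomal bins gave p = 0.00099. Per cluster of annotated TSSs, X carried 0.283 peaks and the autosomes 0.162, a ratio of 1.75 (1.49 to 2.03). With only bins of at least 20 protein-coding TSSs, 23 on X and 94 on the autosomes, the ratio per Mb was lower, 1.42 (1.18 to 1.66).

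**Figure D3:**
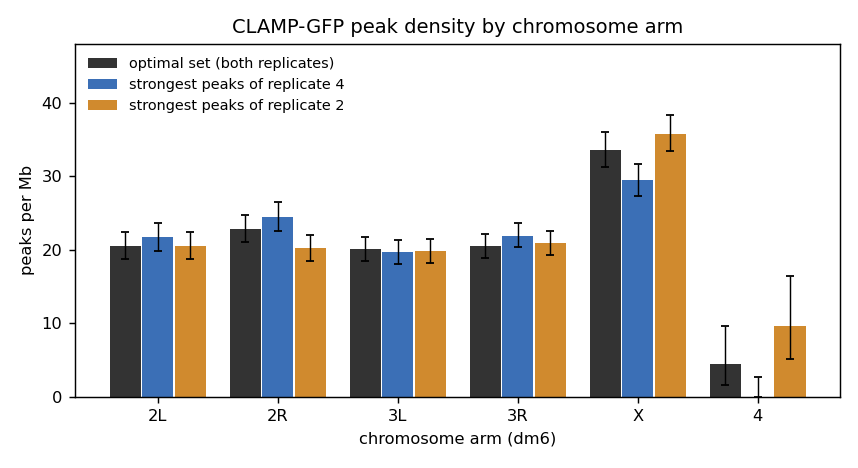
Peaks per Mb on each chromosome arm (dm6) for the optimal set and for the 3077 strongest peaks of each replicate, with exact Poisson 95% intervals as error bars. X lies above each autosomal arm in all 3 sets, at 33.6, 29.4 and 35.8 peaks per Mb.

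X peaks were more numerous but not detectably stronger in the optimal set. Their median signal was 285 on X and 267 on the autosomes, a ratio of 1.06 (bootstrap 95% interval 0.961 to 1.16; two-sided permutation p = 0.194). The replicates taken alone gave separate intervals. Their lists also differed in coding-exon peaks, which had a low median signal in the optimal set (134, against 273 for all peaks). These made up 19.2% of autosomal and 6.06% of X peaks in replicate 4, and 0.405% and 1.07% in replicate 2. The signal ratio was not computed without them. In replicate 4 alone X peaks had the higher median, 204 against 146, a ratio of 1.40 (1.27 to 1.52; permutation p = 1e-05, the smallest that 100000 resamples can give). In replicate 2 alone the ratio was 0.955 (0.882 to 1.03; permutation p = 0.323).

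CLAMP peaks were concentrated at gene starts. Summits within 500 bp of an annotated TSS made up 35.3% of the optimal peaks, against 13.1% of random positions on the same arms, a 2.70-fold difference (two-sided permutation p = 0.001998, the smallest that 1000 random sets can give). A further 36.6% were in introns, 14.8% between genes, 7.75% in coding exons, 2.47% in 5' UTRs and 1.99% in 3' UTRs. The coding-exon share differed between the strongest peaks of replicate 4 (16.2%) and of replicate 2 (0.588%). Promoters took 58.5% of the 300 strongest peaks and 24.0% of the 1075 weakest. The promoter fold was 2.70 in replicate 4 and 2.88 in replicate 2 taken alone.

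GA repeats marked the summits. An uninterrupted GA run of 8 bp or more lay within 100 bp of 34.4% of summits and in 3.31% of equal windows 1000 bp to each side, a 10.4-fold difference. In 1007 pairs of a summit and its flank the summit alone held the run, and in 59 the flank alone (exact binomial p = 1.64e-223, two-sided). The share was 28.1% in replicate 4 and 35.7% in replicate 2, 9.30 and 11.5 times that of their flanks. Of the 1515 peaks over 1000 bp from any TSS, 35.6% held the run. By place it was at 40.1% of intron and 32.0% of intergenic summits, but at 7 of 238 in coding exons (2.94%). Peaks with a run of 8 to 11 bp had a median signal of 343, those with 12 to 19 bp 307, those with 20 bp or more 315.5 and those with no run of 8 bp 240, so signal did not rise with run length beyond 8 bp.

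X peaks held the GA run more often than autosomal peaks. It was present at 42.8% of X summits and 31.5% of autosomal summits, an odds ratio of 1.62 (95% interval 1.37 to 1.92; Fisher's exact test, two-sided, p = 1.51e-08). X also had more GA runs of 12 bp or more, 737 of them at 31.3 per Mb, against 1708 at 15.7 per Mb on the autosomes. Runs were counted singly, and the tests below treat them as independent, though neighbouring runs can share a summit. Of those runs, 29.6% on X and 22.9% on the autosomes had a summit within 200 bp, an odds ratio of 1.41 (1.16 to 1.73; Fisher's exact test, two-sided, p = 0.000527). For runs of 12 to 13 bp 25.9% were occupied on X (exact binomial 95% interval 19.9 to 32.6%) and 16.8% on the autosomes (13.9 to 20.1%). For runs of 20 to 29 bp the values were 28.5% (21.6 to 36.2%) and 34.8% (29.4 to 40.6%), and for the 22 X and 36 autosomal runs of 30 bp or more 54.5% (32.2 to 75.6%) and 33.3% (18.6 to 51%). The occupancy odds ratio did not pass the test for runs of 16 bp or more (1.19, 0.897 to 1.57), nor with the 1538 strongest optimal peaks (1.22, 0.95 to 1.56).

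**Figure D4:**
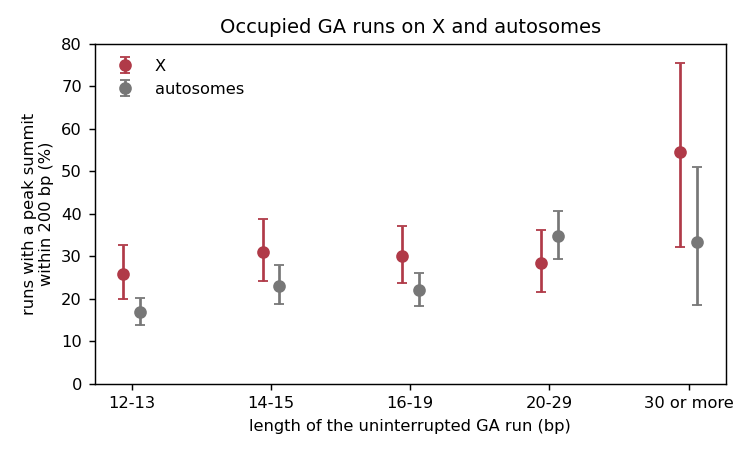
Percent of uninterrupted GA runs with an optimal peak summit within 200 bp, by run length in bp, for X and the autosomes; points are shares and bars exact binomial 95% intervals. X lies above the autosomes for runs of 12 to 19 bp and of 30 bp or more, and the autosomes are higher for runs of 20 to 29 bp; the intervals overlap in every class.

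Both roX genes, which encode the RNAs of the dosage compensation complex, carried a CLAMP peak inside the gene. At lncRNA:roX1 (FBgn0019661, X:3857230 to 3862697) the summit at X:3861305, in an exon, had a signal of 2888 and ranked 88. It ranked 92 in replicate 4 and 75 in replicate 2. At lncRNA:roX2 (FBgn0019660, X:11579065 to 11580432) the summit at X:11580250, in an exon and 1185 bp from the TSS, had a signal of 320 and ranked 1322. This roX2 summit ranked 471 in replicate 2 and had no counterpart within the gene in the list of replicate 4; the GC content around it was 35.7%, against 52.7% at the roX1 summit. Clamp itself (FBgn0032979, 2L:22165720 to 22169143) had a peak of signal 282 in its 5' UTR at 2L:22168641. The list of replicate 2 held 4 peaks within Clamp, the strongest at 2L:22169128 with rank 207, and that of replicate 4 held none.

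CLAMP peaks favoured the genes of early embryonic patterning. Of 13865 protein-coding genes on the arms, 1424 (10.3%) had an optimal peak within 1 kb of a TSS. Among 20 gap and pair-rule segmentation genes 16 had one (80%; Fisher's exact test, adjusted p = 1.2e-11), with oc, opa and btd the strongest; the 4 without were Kr, ftz, kni and knrl. Segment polarity genes had a peak in 9 of 15, among them inv (signal 4734), wg (3284) and en (3183). Of 12 regulators of zygotic genome activation 8 had one, including opa, cad (3208) and Trl (2326), which encodes the GA-binding protein GAF, and zld. In the last 2 lists the adjusted Fisher's exact p was 3.1e-05. Members of the Hox list had a peak in 6 of 8, led by abd-A (3434), lab (3015) and Dfd (2856), with an adjusted Fisher's exact p of 8.81e-05; against length-matched genes the list did not pass (28.4% expected, adjusted permutation p = 0.0668). Ubx and Antp, the members without one at a TSS, held 6 and 10 peaks within the gene.

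Genes for GA-binding and insulator proteins carried a peak in 9 of 17 cases (adjusted p = 6.07e-05, Fisher's exact test), with pzg (2900), mod(mdg4) (2368) and Trl in front. Neural progenitor regulators had one in 9 of 18 (adjusted Fisher's exact p = 8.81e-05), led by D, SoxN (1774) and grh (1258). Among neuronal differentiation genes 8 of 15 had a peak (adjusted Fisher's exact p = 0.000116), among them fne (1813), Syx1A (878) and elav (407), and the peaks at Syx1A and elav were missing from the list of replicate 4. Muscle genes had one in 8 of 21 (adjusted Fisher's exact p = 0.00188), led by ap, lbe and Tm1 (1255), and dorsoventral patterning genes in 7 of 17 (0.00216), led by Dr (3238), pnr (1933) and brk (1555). Ecdysone response genes had one in 6 of 13 (0.00228; Eip75B 973, ftz-f1 842, Blimp-1 760). Polycomb and trithorax group genes had one in 8 of 28 (0.0115; ph-p 3426, Psc 3231, Su(z)2 3171). Notch pathway genes had one in 6 of 20 (0.0236), led by E(spl)mbeta-HLH (1127), E(spl)malpha-BFM (1047) and E(spl)m8-HLH (986) of the Enhancer of split complex. The genes of that complex are neighbours on 3R and are not independent. Of the lists in this paragraph, only those of GA-binding and insulator proteins and of neural progenitor regulators also passed against length-matched genes.

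At the other end, none of 119 odorant and gustatory receptor genes had a peak (adjusted Fisher's exact p = 3.1e-05; odds ratio at most 0.273 by its 95% interval). Many of them lie close together, such as Gr22a to Gr22e on 2L, and Gr64b and Gr64c have the same annotated span. The genes are therefore not all independent, which neither this test nor the length-matched comparison allows for. In all, 14 of 26 lists passed the test. These include the 111 replication-dependent histone genes, none with a peak, but as they form 1 repeat cluster and are not independent, no depletion is inferred from that call. Of the others 12 had a higher and 1 a lower share of genes with a peak. Against random genes matched on gene length 6 of them passed: gap and pair-rule segmentation, segment polarity, zygotic activation regulators, GA-binding and insulator proteins, neural progenitor regulators and odorant and gustatory receptors. The Hox, neuronal differentiation, muscle, dorsoventral, Notch, ecdysone, Polycomb and histone lists did not, with adjusted permutation p from 0.0668 to 0.303.

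**Figure D5:**
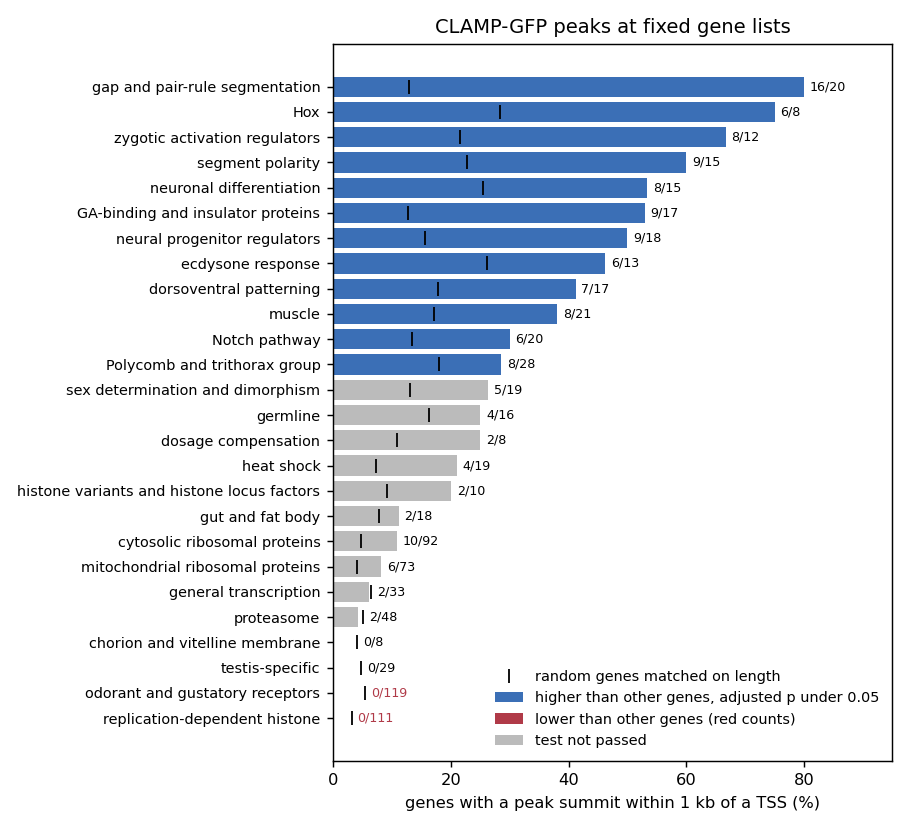
Percent of the genes of each of 26 lists with an optimal peak summit within 1 kb of a TSS; the counts stand beside the bars, colours show the outcome of Fisher's exact test with Benjamini-Hochberg adjustment, and ticks show the mean share of random genes matched on length. Gap and pair-rule segmentation genes lead with 16 of 20, and odorant and gustatory receptor genes have 0 of 119; the call for replication-dependent histone genes, which form 1 repeat cluster, is not interpreted.

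The other 12 lists did not pass in the optimal set. Of 8 dosage compensation genes only lncRNA:roX1 and Clamp had a peak within 1 kb of a TSS (25%; adjusted Fisher's exact p = 0.267). Sex determination genes had one in 5 of 19 (0.0673, same test), at run (1262), upd1 (493), fru (220), sc and fl(2)d. Germline genes had one in 4 of 16, at zpg (509), ovo (506), tud (223) and nanos, and heat shock genes in 4 of 19, at Hsp68 (1025), Hsc70-4 (569), Hsp27 (398) and Hsp22. Histone variants and histone locus factors had one in 2 of 10, at His3.3B (665) and cid (133), and gut and fat body genes in 2 of 18, at fkh (1567) and srp (988). Cytosolic ribosomal protein genes had a peak in 10 of 92, led by RpL7A (1710) and RpS28a (615), and mitochondrial ribosomal protein genes in 6 of 73, led by mRpL53 (2256), mRpL17 (826) and mRpL1 (169). Proteasome genes had one in 2 of 48 (Rpn8 851, Prosalpha5 209) and general transcription genes in 2 of 33 (Polr2I 405, Polr2E 133). None of 29 testis-specific and none of 8 chorion and vitelline membrane genes had one. The peaks at ovo and Hsc70-4 had no counterpart in the list of replicate 4, and those at cid and Polr2E none in that of replicate 2. A peak counted within 1 kb of a TSS can lie in a neighbouring gene. The summit named by Polr2I was 939 bp from its TSS and within su(Hw). Those named by RpL7A, RpS28a and mRpL17 were 931, 638 and 838 bp from the TSS, outside the named gene and in a 5' UTR or intron of another.

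Of these 12 lists 5 passed in 1 or 2 other settings. In replicate 4 alone cytosolic ribosomal protein genes had a peak in 18 of 92 (19.6% against 11.4% of other genes) and histone variants and histone locus factors in 4 of 10 (adjusted Fisher's exact p = 0.0329 for each); in replicate 2 alone the counts were 10 and 1. Proteasome and general transcription genes also moved from below to above the average in replicate 4 alone, to 7 of 48 (14.6%) and 5 of 33 (15.2%), without passing (adjusted Fisher's exact p = 0.556 and 0.495). Germline genes passed in replicate 2 alone (5 of 16, adjusted Fisher's exact p = 0.0347) and with peaks within the gene or 1 kb of it (6 of 16, 0.0361). Sex determination genes passed within 500 bp of a TSS (5 of 19, adjusted Fisher's exact p = 0.0138). Testis-specific genes passed as lower with peaks within the gene or 1 kb of it (0 of 29, adjusted Fisher's exact p = 0.0282). Against length-matched genes the cytosolic list had 10.9% in the optimal set, with 4.78% expected (adjusted permutation p = 0.0779).

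The replication-dependent histone genes, a locus where CLAMP is known to bind, had few peaks in these lists. The interval that they span on 2L (21416953 to 21541681, 125 kb, 111 genes) held no optimal peak. Each of the 2 replicate lists and the pooled list held 1 peak there, at 2L:21425125 or 2L:21425127 near the start of the interval. It ranked 2069 in replicate 2, within its 3077 strongest, 3727 in replicate 4 and 25770 in the pooled list. The interval consists of repeated gene copies, and how reads matching several copies were treated is not given in the sources used here, so no occupancy was inferred for it.

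The optimal set was nearly the same size in both genome builds, with 3077 peaks in dm6 and 3025 in dm3. X carried 790 and 794 of them. The highest signal was 7590.5 in dm6 and 7588 in dm3, and the median 273 and 275. The median peak width was 410 bp in dm6 and 404 bp in dm3. The lists given to the reproducibility step held 30000 regions each, except that of replicate 2 in dm3, which held 7453.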

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

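In this part, the test of the 300 strongest peaks was chosen only after the result had been seen. Peaks on chromosome 4, which was outside the comparisons of the report, stood out because the replicates differed. The optimal set held 6 peaks there. The 30000-region lists, which contain background regions, held 326 regions there in replicate 2 and 3 in replicate 4. Only 13 of the 326, and 0 of the 3, were among the 3077 strongest peaks of their replicate. In the list of replicate 2, chromosome 4 held 241.8 regions per Mb, within the range of the 5 arms (201.1 on X to 249.6 on 2L). In that of replicate 4 it held 2.23 per Mb, against 207.2 on 3L to 248.2 on 2R. The optimal set in dm3 also held 5 peaks on heterochromatic or unplaced sequence, which were not analysed further.

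The pattern behind the chromosome 4 counts was wider: 152 of the 1000 strongest peaks of replicate 2 were missing from the whole list of replicate 4, among them the roX2 peak and the 2 strongest of its 4 peaks at Clamp. Loss at the end of the list of sites weak in both replicates is argued against as the whole cause. Of the 300 strongest peaks of replicate 2, 5% were already missing (exact binomial 95% interval 2.83 to 8.11%). A site strong in replicate 2 can still be weak in replicate 4 and fall below the end of its list, which this test cannot exclude. A candidate explanation is poor recovery of AT-rich DNA in replicate 4. The missing sites had a median GC content 6.19 percentage points below that of the found sites, 40.7% against 46.9% (a difference of -6.19, bootstrap 95% interval -6.99 to -5.19; permutation p = 1e-05, the smallest that 100000 resamples can give). In 4 equal parts by GC content, 38.3% of the most AT-rich sites were missing and 1.64% of the most GC-rich, and chromosome 4 as a whole has a GC content of 35.2%. Both replicates belong to the same group, so the design gives no biological difference to set against this.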

How the results depend on the processing

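Tests on peaks found in both replicates' lists were chosen only after the data had been seen. The density, promoter, GA-run fold and GA-run odds results kept their direction and their side of the threshold under every alternative run. Taking each replicate alone gave 1.35 to 1.76 for the density ratio, 2.70 to 2.88 for the promoter fold, 9.30 to 11.5 for the GA-run fold, 1.53 to 2.15 for the GA-run odds ratio, 1.39 to 1.40 for the occupancy odds ratio, 0.955 to 1.40 for the signal ratio and 15 to 16 gene lists. The signal ratio passed the permutation test without replicate 2 (1.40) and in no other setting; the cause was not tested. The occupancy odds ratio fell short of the threshold with runs of 16 bp (1.19) and with the 1538 strongest peaks (1.22). These settings leave fewer runs or fewer occupied runs to test, but the ratio itself was also below the 1.41 of the main set. For runs of 20 to 29 bp the occupied share was lower on X (28.5%) than on the autosomes (34.8%). Matching on gene length left 6 of 14 gene lists, with the other settings at 14 to 16. Over all settings, list by list, the 14 called lists passed in 90 comparisons and did not in 8, all of these against length-matched genes (the histone list, 1 repeat cluster, is among the 14 and is not interpreted), and the 12 others passed in 6 of 84 (germline in 2, and cytosolic ribosomal, histone variant, sex determination and testis-specific lists in 1 each). Replicate overlap ranged from 56.2% at 100 bp to 71.3% with 1538 peaks per list. With peaks found in both whole lists, background regions included, the density ratio was 1.77 and the occupancy odds ratio 1.46. Depth is unknown and 2 replicates cannot separate a library effect from chance.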

Other observations

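In this part, the counts by place in the gene and the 6-mer counts were chosen only after the data had been seen. CLAMP peaks on X lay in 3' UTRs more often than those on the autosomes. Of 790 X peaks 44 had their summit in a 3' UTR (5.57%), and of 2281 autosomal peaks 17 (0.745%), an odds ratio of 7.86 (95% interval 4.36 to 14.8; Fisher's exact test, adjusted p = 1.57e-13 over 7 places). Random positions fell in 3' UTRs at 5.81% on X and 4.17% on the autosomes, so the share on the autosomes was below that of random positions. On X it was 3.61% in replicate 4 and 8.78% in replicate 2, on either side of the random share. The odds ratio was 8.07 in replicate 4 and 12.5 in replicate 2. Of the 44 peaks 24 held a GA run of 8 bp or more and 34 had a match in both replicates' whole lists, which contain background regions. Some of these matches were weak, down to rank 24572 in replicate 4 and rank 14882 in replicate 2. The strongest was in the 3' UTR of Lim1 at X:8757953, 27400 bp from the nearest TSS, and the next were in those of CanA-14F (X:16562469, with a 29 bp GA run) and Inx2 (X:7000630).

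Coding exons differed between the replicates. They held 9.29% of autosomal and 3.29% of X optimal peaks. The odds ratio, X against autosomes, was 0.272 in replicate 4, while in replicate 2 the shares were 0.405% and 1.07% (odds ratio 2.65; adjusted Fisher's exact p = 0.0821), so the lower share on X rests on replicate 4. Among the strongest peaks of each replicate they held 499 of 3077 (16.2%) in replicate 4 and 18 of 3064 (0.588%) in replicate 2. The 238 coding-exon peaks of the optimal set had a median GC content of 57.3%, a median signal of 134 against 273 for the whole set, and a GA run in 7 cases (2.94%).

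The 6-mer with the largest difference in percentage points between summits and flanks was AGAGAG, in 55.5% of summit windows and 10.6% of flanks. GAGCGA, which breaks the GA alternation with a C, came next, in 50.7% and 9.65%. CAGGTA, the core of the motif of the zygotic activator Zelda, was in 4.75% of summit windows and 4.56% of flanks.

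Most optimal peaks, 2014 of 3071, lacked an uninterrupted GA run of 8 bp. Their promoter share was 35.1%, against 35.7% with the run, a difference of -0.563 percentage points (Fisher's exact p = 0.781). It was thus no higher than with the run. Both shares exceeded the 13.1% of random positions, so the comparison cannot decide whether general enrichment at promoters gave some of these peaks. Coding-exon peaks, 7 of 238 with a run, fell mostly in the group without it, which lowers that group's promoter share. Interrupted repeats may account for part of the peaks without the run. A 10 bp GA repeat with 1 mismatch was 5.15 times as frequent at their summits as in flanks (25.4% against 4.94%). That left 1502 peaks with neither, of which 38.9% held GAGCGA against 9.52% of flanks.

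For the higher density on X, base composition and GA-run number were weighed as explanations. X has more GA runs of 12 bp or more per Mb, but these were also occupied more often there (odds ratio 1.41, 95% interval 1.16 to 1.73). This argues against the number of such runs as the whole cause, although the excess was not detected for runs of 16 bp or more (1.19). Only 16.1% of summits held a run of 12 bp or more, and the occupancy of shorter runs was not tested. The interval also treats neighbouring runs as independent, though they can share a summit. GC content as the whole cause is argued against too: standardised over 10 classes of GC content in 1 kb windows, the density ratio was 1.66 (bootstrap 95% interval 1.37 to 1.97), against 1.61 before. The ratio was not even across the classes: it fell from 3.84 (2.08 to 7.45) in the most AT-rich class to 1.3 (0.942 to 1.73) and 1.05 (0.702 to 1.42) in the 2 most GC-rich, where no excess on X was detected. These intervals were added after the data had been seen. The optimal set held 212 coding-exon peaks on the autosomes and 26 on X, with a median GC content of 57.3%. Their lower share on X rested on replicate 4. The classes were not computed without these peaks, so whether they lowered the ratio in the GC-rich classes was not tested. As the embryos were of both sexes in 1 pool, a link with dosage compensation in males was not tested and stays open.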
